A study of Mus musculus with 9 samples.

How the data were processed

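RNA was measured by poly(A) RNA sequencing in RAW264.7 cells, a mouse macrophage-like cell line, in 9 libraries that the labels place in 3 groups of 3. Mock cells are the untreated reference. The group called M1 received lipopolysaccharide (LPS) at 100 ng/ml and mouse interferon gamma at 50 ng/ml. The group called I received the same with potassium iodide at 20 mM during polarization. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

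The values deposited by the authors are FPKM, that is fragments scaled by gene length and library total. No header names this unit, and it was read from the values. Per the submitters' processing notes, the tools were fastp 0.20.1, HISAT2 2.2.1 and featureCounts 2.0.1 of the Subread package, with the GRCm38 genome. Their settings, strand use and gene annotation are not given in the sources used here. Each library holds 12474 rows with 12467 distinct gene names, of which 7 are listed 2 times and were kept as separate rows. Every row has a value above 0 in all 9 libraries, so genes at 0 in any library are not analysed here, and a gene silent in 1 group and switched on in another can be missing from every count below.

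Gene lengths came from the GENCODE vM21 annotation of GRCm38, which matched 12204 rows (97.8%). FPKM multiplied by the summed exon length gave whole multiples of 1 step per library in 98.4% to 98.6% of values, within 0.05 fragments. The steps put the library totals between 17431070 and 25470730 fragments. At that depth a single fragment on a gene of 1 kb is worth between 0.039 and 0.057 FPKM, so the counting error is small for genes above a few FPKM. Fragments were whole in all libraries for 11996 genes. Scaling was by the library total alone.

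The analysis was fixed before the data were examined, with a count model for raw counts and limma on log values for any normalized unit. The files held FPKM and not counts, so limma 3.58.1 in R 4.3.3 was used on log2(FPKM + 1). Rows with an FPKM of at least 0.5 in at least 3 libraries were tested, which kept 11156 and removed 1318. This filter was chosen after the values had been seen. One linear model was fitted to all 9 libraries with a term per group, and contrasts gave M1 vs Mock, I vs M1 and I vs Mock with moderated variances and an intensity trend. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Fold values printed as ratios are ratios of group mean FPKM.

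There were 29 gene lists with 510 genes, 22 on pathways and 7 on cell types, written before the data were examined. Of these genes 424 are in the files, and the 23 lists with at least 3 tested genes were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes. The plan named log2 counts as the input, and log2(FPKM + 1) was used instead. The calls were repeated with a correlation estimated per list and with fry, which tests whether the genes of a list move, on balance, one way. The median of a list is given relative to the median of all tested genes. The genes named in the text follow a rule also written beforehand. For M1 vs Mock and for I vs M1 it takes the 5 largest rises and the 5 largest falls among called genes whose mean reaches 10 in the higher group (CPM in the rule, applied here to FPKM) and whose groups do not overlap, up to 3 members of each list with the smallest p, and a set of key genes in every comparison. The text names only part of the genes that the rule takes, and that part was picked after the values had been seen. Of the key genes, Il12b, Mrc1, Slc5a5 and Slc26a4 are not analysed here, and Arg1 lay below the filter.

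To compare the responses to polarization and to iodide, 100 data sets were simulated in which the M1 and I libraries shared the M1 means and differed only by the fitted variance, since both comparisons use the same M1 libraries. The plan drew only the I libraries. The M1 libraries were drawn anew as well, a change made after the first run, because otherwise the chance shared by both comparisons was left out. The models were also run on simulated data. In 10739 simulated genes with 200 changed between I and M1, the model recovered 54% of genes changed by 0.25 on the log2 scale, 87.8% of those changed by 0.5, 94% of those changed by 1 and 97.9% of those changed by 2. Of the 169 calls, 5 were false (3%). None of the 20 lists of unchanged genes was called, and the raised list was called. The simulated genes were drawn independently of each other, so list calls under correlation between genes were not tested. The 200 changed genes were also far fewer than the 7157 called for I vs M1 in the real data.

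The alternatives tried were median-of-ratios (RLE), upper quartile, trimmed mean of M values (TMM) and quantile scaling, limma-voom on the recovered fragments, no filter, a filter of 1 FPKM, a pseudocount of 0.1, a threshold of 0.01, a minimum log2 fold change of 1, the 6 libraries of a comparison alone, the replicate number as a block, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9. Gene positions are 1-based GRCm38 coordinates from GENCODE vM21.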

Results

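The transcriptomes of RAW264.7 macrophages were compared in 3 states, with 3 libraries each. Mock cells were untreated, M1 cells were polarized with LPS and interferon gamma, and I cells were polarized in the presence of 20 mM potassium iodide. The series asks how iodide ions change gene expression during M1 polarization. The library totals recovered from the FPKM values were 17431070 to 25470730 fragments in Mock, 17765680 to 21867430 in M1 and 18370400 to 21202240 in I. Libraries of a group had a Pearson r of 0.9973 to 0.9977 across genes on the log2 scale. Each pair differed by more than sampling noise, with a mean chi-square per gene of 2.04 to 3.73, so no library was a copy of another. The first principal component held 87.8% of the variance and separated Mock from the polarized groups, and the next held 9.5% and separated I from M1.

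Rises and falls are ranked here among genes that the naming rule admits, with a mean of at least 10 FPKM in the higher group. The largest rise on the log2(FPKM + 1) scale in M1 was that of Csf3, which encodes granulocyte colony-stimulating factor (ENSMUSG00000038067.2, chromosome 11, 98701263 to 98703629). Csf3 rose from 0.54 ± 0.22 to 1984 ± 30 FPKM (SD, n = 3 in each group here and below). Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826.8, chromosome 11, 78920787 to 78960254), rose 65.3-fold, from 22.2 ± 0.43 to 1447 ± 16 FPKM. Upp1, a uridine phosphorylase, rose from 1.63 ± 0.14 to 411.1 ± 11 FPKM. Similar rises were seen in the iron-siderophore binding protein gene Lcn2 from 0.76 ± 0.19 to 225 ± 3.5, and the monocyte attractant Ccl2 from 4.04 ± 0.19 to 404 ± 12. The protease inhibitor gene Serpina3f rose from 0.15 ± 0.023 to 149 ± 0.12 FPKM. Its level is uncertain because close paralogs can share its reads. The largest fall under the same limit was in Ranbp3l (36.7 ± 0.2 to 0.73 ± 0.048 FPKM). It was followed by the cell division genes Ccnb2 (41.1 ± 1.9 to 1.1 ± 0.3), Cdc20 (46.8 ± 2.3 to 1.43 ± 0.28) and Mki67 (58.2 ± 1.1 to 2.32 ± 0.25), and the integrin gene Itga4 (215 ± 3.7 to 12 ± 0.48).

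Of 11156 genes tested for M1 vs Mock, 3405 were higher and 6166 lower in M1 at a limma adjusted p under 0.05, and 1585 were not called. At least 2-fold changes were seen in 756 genes that rose and 1794 that fell. The median gene fell by 0.23 on the log2 scale. Among genes with a matched length, which leave out the mitochondrial genome, the 10 with most fragments over all libraries held 4.13% to 4.2% in Mock and 10.6% to 10.9% in M1. Most of the libraries are polarized, so this choice favours genes that rise in M1, and the top genes of Mock alone were not taken. With RLE scaling the median shift was 0.01 and the split was 4810 higher and 4749 lower, with 1163 and 1163 at least 2-fold, so the share of rises depends on the scaling.

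Inflammatory genes rose together in M1. Of 23 cytokine and chemokine genes 21 rose and 2 fell, with a median log2 fold change 3.1 above that of all genes (camera adjusted p = 4.04e-10). Il1b rose from 0.22 ± 0.041 to 54.6 ± 1.2 FPKM and Il6 from 0.23 ± 0.11 to 32.3 ± 1. Large rises also occurred in the interleukin 1 receptor antagonist gene Il1rn from 17.3 ± 0.4 to 1039 ± 30, and Tnf 6.26-fold from 168 ± 5.9 to 1049 ± 15. The other direction was taken by Cxcl10, an interferon-inducible chemokine, which fell from 80.5 ± 3.1 to 14.2 ± 0.23 FPKM (log2 fold change −2.42 ± 0.03 SE, adjusted p = 9.61e-14). Among 16 M1 markers 14 rose and 2 fell (median 2.95 above all genes, adjusted p = 8.43e-08). They included the prostaglandin synthase gene Ptgs2 (31.1 ± 0.86 to 1945 ± 123.2 FPKM), the cytokine signalling inhibitor Socs3 (5.08 ± 0.34 to 260 ± 7.4) and the costimulator Cd86 (0.44 ± 0.11 to 7.62 ± 0.75). In the NF-kB and Toll-like receptor list 19 of 28 genes rose and 6 fell (adjusted p = 1.37e-05). Among them were the feedback inhibitor Nfkbia (75.3 ± 2 to 477 ± 8.9 FPKM) and Nfkbiz (14.9 ± 0.51 to 79.2 ± 0.57).

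Glycolysis and hypoxia-response genes rose in M1, 16 of 22 with 4 falls (adjusted p = 6.51e-06). The glycolysis activator Pfkfb3 rose from 6.63 ± 0.23 to 64.2 ± 0.62 FPKM, the glucose transporter Slc2a1 from 69.2 ± 1.7 to 375 ± 11 and the hexokinase Hk1 from 34.8 ± 0.82 to 87 ± 2.8. Of 17 p53 targets 14 rose and 2 fell (adjusted p = 1.54e-05). Mdm2 went from 34.4 ± 0.77 to 121 ± 1.5 FPKM and the cyclin-dependent kinase inhibitor Cdkn1a from 128 ± 4.3 to 364 ± 11. Of 23 lysosome genes 17 rose and 3 fell (adjusted p = 5.99e-06). The protease gene Ctsd went from 252 ± 4.2 to 800 ± 15 FPKM. Antigen presentation genes rose in 13 of 17 cases with 2 falls (adjusted p = 5.66e-05, but adjusted p = 0.14 with an estimated correlation). Examples were the peptide transporter Tap1 (39.5 ± 0.22 to 82.5 ± 2.5 FPKM) and H2-D1 (252 ± 2.4 to 550 ± 15), whose reads can be shared with other class I genes. The heme oxygenase Hmox1 rose from 129 ± 4.4 to 746 ± 9.1 FPKM. Its list of NRF2 targets had 12 of 19 genes higher and 7 lower (adjusted p = 0.0307), a call lost with RLE scaling (adjusted p = 0.0626) and with an estimated correlation (adjusted p = 0.159). The NADPH oxidase and antioxidant list had 7 of 13 higher and 4 lower (adjusted p = 0.022, and adjusted p = 0.14 with an estimated correlation). Quantile scaling also removed that call (adjusted p = 0.811).

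Cell cycle genes fell in M1, 29 of 30, and 28 of them at least 2-fold (median log2 fold change −2.25 relative to all genes, adjusted p = 8.43e-08). Ccna2 fell from 24.9 ± 0.8 to 0.84 ± 0.12 FPKM and the replication helicase gene Mcm7 from 23.8 ± 0.2 to 2.72 ± 0.15. Interferon-stimulated genes fell as well, 29 of 35 with 6 rises (adjusted p = 0.00144, and adjusted p = 0.127 with an estimated correlation). Ifit1 fell from 84.5 ± 0.66 to 12.3 ± 0.65 FPKM, Cmpk2 from 185 ± 3.6 to 43.8 ± 0.14 and Parp14 from 85.6 ± 0.92 to 21.7 ± 0.79. With RLE scaling 23 of the 35 were called lower. Of 13 lipid genes under the liver X receptor 12 fell (adjusted p = 0.00376, and adjusted p = 0.14 with an estimated correlation). The fatty acid synthase gene Fasn went from 84.6 ± 1.3 to 6.64 ± 0.28 FPKM and the cholesterol exporter Abcg1 from 48.6 ± 0.51 to 10.5 ± 0.31. Endoplasmic reticulum chaperones fell in 14 of 16 cases (adjusted p = 0.00137, and adjusted p = 0.0691 with an estimated correlation). Hsp90b1 went from 240.5 ± 1.6 to 85.7 ± 5.2 FPKM and Hyou1 from 78.2 ± 1.1 to 23.4 ± 0.71. Osmotic response genes fell in 8 of 9 cases. Among them were the aldose reductase Akr1b3 (61.8 ± 0.54 to 11.7 ± 0.12 FPKM), the inositol transporter Slc5a3 (38.8 ± 0.62 to 7.52 ± 0.13) and the amino acid transporter Slc38a2 (105 ± 0.91 to 22.4 ± 0.83). That list's adjusted p of 0.0411 became 0.0951 with RLE scaling and 0.135 with an estimated correlation.

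Of the 23 lists 14 were called for M1 vs Mock, and 7 held with an estimated correlation. They were cytokines, M1 markers, NF-kB, glycolysis, p53 targets and lysosome higher and cell cycle lower (adjusted p = 0.0359 to 0.0468). The lists not called were M2 markers (4 higher and 5 lower of 9), interferon-inducible GTPases (6 and 8 of 18), inflammasome genes (6 and 7 of 13), tricarboxylic acid cycle and respiratory chain genes (8 and 14 of 26), cholesterol synthesis (7 and 9 of 20), ATF4 and CHOP targets (5 and 12 of 17), heat shock genes (1 and 8 of 10), macrophage identity genes and osteoclast markers. The heat shock list was called lower with quantile scaling (adjusted p = 0.0105) and with limma-voom (adjusted p = 0.0283). In the respiratory list Idh2, a mitochondrial isocitrate dehydrogenase, fell from 48.2 ± 1.3 to 13.4 ± 0.28 FPKM. Counts adjusted over the list alone were the same as over all genes for each list in this comparison.

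Macrophage identity genes moved both ways in M1, 6 higher and 5 lower of 12, and the list was not called (adjusted p = 0.277). The growth factor receptor Csf1r fell from 343 ± 3.4 to 69.8 ± 1 FPKM and the lysozyme Lyz2 from 3155 ± 43 to 1138 ± 31, while Adgre1, which encodes F4/80, rose from 21.7 ± 0.78 to 103 ± 2.3. Of 5 osteoclast markers 3 rose and 2 fell, and the list was not called (adjusted p = 0.37). Dcstamp went from 22.4 ± 0.64 to 47.7 ± 0.26 FPKM, Acp5 from 0.36 ± 0.082 to 2.94 ± 0.037 and Nfatc1 from 8.24 ± 0.37 to 3.73 ± 0.073. The dendritic cell marker Cd83, the only tested gene of its list, rose from 9.95 ± 0.76 to 24.4 ± 0.34 FPKM. The other members in the files, Zbtb46, Itgax and Xcr1, lay below the filter. The lymphocyte gene Lck was at 4.96 ± 0.34 in Mock and 3.58 ± 0.34 in M1, a fall not called with RLE scaling. No gene of the neutrophil, fibroblast and epithelial lists and 1 of 18 genes on iodide transport and halide enzymes is in the files, so these were not tested.

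**Figure D1:**
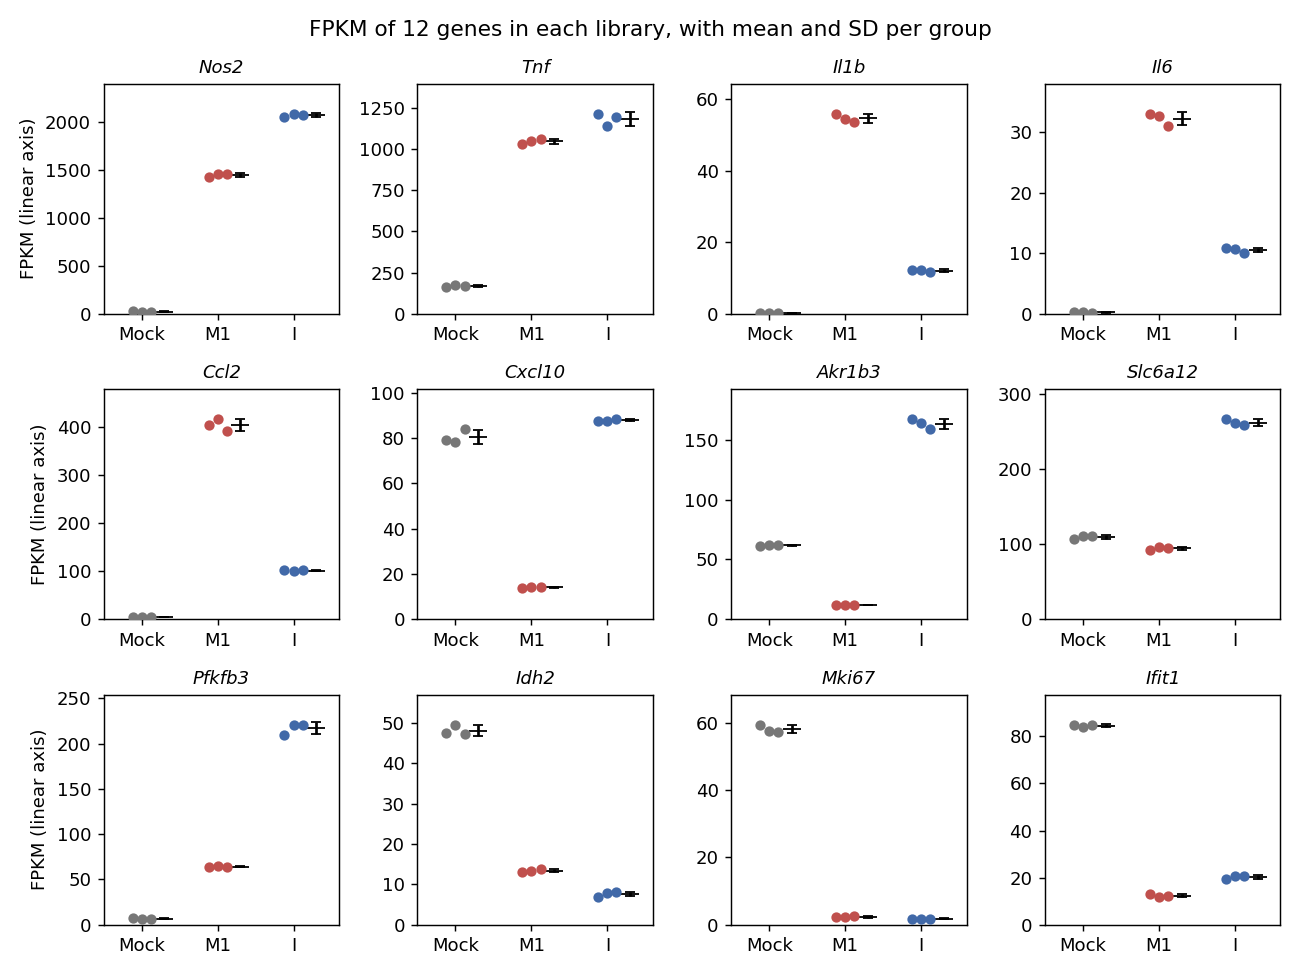
FPKM (vertical axes, linear, from 0) of 12 genes in the Mock, M1 and I groups, with each point 1 library and the bar the mean ± SD of 3 libraries. Nos2 rises from 22.2 in Mock to 1447 in M1 and 2070 in I, Il1b is at 54.6 in M1 and 12 in I, and Akr1b3 is at 11.7 in M1 and 164 in I.

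The comparison of I with M1 sets polarization with potassium iodide against polarization without it. No library received another salt, so effects of iodide, potassium and osmolarity cannot be told apart. Changes with iodide below are changes with potassium iodide. Akr1b3, the aldose reductase that makes the organic osmolyte sorbitol (ENSMUSG00000001642.18, chromosome 6, 34302434 to 34317478), showed the largest rise under the same limit and scale, from 11.7 ± 0.12 to 164 ± 4.1 FPKM (log2 fold change 3.7 ± 0.026 SE, adjusted p = 1.67e-14). As ratios of means the rises of Clca2 (36.9-fold) and Ranbp3l (17.6-fold) exceeded that of Akr1b3 (14.0-fold). Clca2, a regulator of chloride conductance, rose from 0.28 ± 0.035 to 10.3 ± 0.55 FPKM. Next came the MAP kinase phosphatase gene Dusp2 from 17.3 ± 0.62 to 152 ± 4.2, Ranbp3l from 0.73 ± 0.048 to 12.9 ± 0.2, and Cxcl10 6.2-fold from 14.2 ± 0.23 to 88 ± 0.39. Under that limit and scale the largest falls were in the chemokine Ccl6 (44.5 ± 1.2 to 5.9 ± 0.39 FPKM) and in Il1a (21.3 ± 2.2 to 2.57 ± 0.17). They were followed by the lipoprotein lipase Lpl (39.1 ± 1 to 5.93 ± 0.14), the arginine synthesis gene Ass1 (13.3 ± 0.18 to 2.01 ± 0.3) and the formyl peptide receptor Fpr2 (18 ± 0.98 to 3.33 ± 0.18). In each of these 10 genes the 3 I libraries lay on the same side of the 3 M1 libraries, as the rule for naming them requires.

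In I vs M1, 2775 genes were higher, 4382 lower and 3999 not called. Most changes were small, with 118 higher and 86 lower at least 2-fold. That 2-fold count and its balance depend on the setting, with 243 higher and 250 lower at a pseudocount of 0.1 and 294 higher and 329 lower with limma-voom. The median gene fell by 0.065 on the log2 scale. With RLE scaling the split was 3478 higher and 3540 lower.

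Iodide moved inflammatory genes in both directions. Of the 23 cytokine and chemokine genes 7 were higher, 11 lower and 5 not called in I, and the list as a whole was not called (adjusted p = 0.642). Il1b fell from 54.6 ± 1.2 to 12 ± 0.43 FPKM, Il6 from 32.3 ± 1 to 10.5 ± 0.4 and Ccl2 from 404 ± 12 to 101 ± 1.2. Nos2 rose further, from 1447 ± 16 to 2070 ± 20 FPKM (log2 fold change 0.52 ± 0.023 SE, adjusted p = 2.08e-08), and Tnf from 1049 ± 15 to 1185 ± 40 (0.17 ± 0.033 SE, adjusted p = 0.000895). Of 16 M1 markers 5 were higher and 10 lower. Among them Socs3 rose from 260 ± 7.4 to 535 ± 8.9 FPKM, while Cd40 fell from 73.7 ± 0.26 to 39.5 ± 1.2 and Cd86 from 7.62 ± 0.75 to 5.81 ± 0.49. Among 9 M2 markers 5 were higher and 4 lower. The receptor gene Il4ra rose from 8 ± 0.25 to 18.2 ± 0.25 FPKM, and the beta-glucan receptor Clec7a fell from 7.59 ± 0.25 to 1.12 ± 0.056. The alternative activation marker Arg1 was at 0.13 ± 0.074 FPKM in Mock, 0.38 ± 0.094 in M1 and 0.28 ± 0.026 in I, below the filter.

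Osmotic response genes rose with iodide, 7 of 9 with 1 fall and 1 not called (median log2 fold change 0.87 above all genes, adjusted p = 6.67e-05, and adjusted p = 0.0747 with an estimated correlation). Besides Akr1b3, the betaine transporter Slc6a12 (chromosome 6, 121343076 to 121365775) rose from 94.5 ± 2.3 to 262 ± 4 FPKM and the chaperone Hspa4l from 12.9 ± 0.1 to 37.7 ± 0.77. Glycolysis and hypoxia-response genes rose in 16 of 22 cases with 2 falls (adjusted p = 3.05e-06, and adjusted p = 0.0747 with an estimated correlation). Pfkfb3 rose 3.38-fold to 217 ± 6.4 FPKM, the growth factor gene Vegfa from 55.4 ± 1.6 to 125 ± 5.8 and the lactate transporter Slc16a3 from 93.8 ± 3.1 to 150 ± 3.6. Tricarboxylic acid cycle and respiratory chain genes fell in 23 of 26 cases with no rise (median −0.28 relative to all genes, adjusted p = 2.69e-06, and adjusted p = 0.0843 with an estimated correlation). Idh2 fell from 13.4 ± 0.28 to 7.62 ± 0.58 FPKM and Uqcrc2 of respiratory complex III from 80.7 ± 1.8 to 57.4 ± 1.3.

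Interferon-stimulated genes were higher with iodide in 20 of 35 cases and lower in 9 (adjusted p = 0.00249, and adjusted p = 0.173 with an estimated correlation). Cmpk2 rose from 43.8 ± 0.14 to 81 ± 1.4 FPKM and Rsad2 from 122 ± 4.3 to 192.5 ± 2.1, while Oasl1 fell from 330.4 ± 5 to 179 ± 1.7. NADPH oxidase and antioxidant genes fell in 10 of 13 cases with 2 rises (adjusted p = 0.00755, and adjusted p = 0.173 with an estimated correlation). The oxidase subunit gene Ncf1 went from 175 ± 1.6 to 110.3 ± 2.6 FPKM, Txnip from 85.3 ± 1.4 to 44.2 ± 1.6 and Sod2 from 31.4 ± 0.35 to 17.5 ± 1.1. NRF2 targets fell in 14 of 19 cases with 4 rises (adjusted p = 0.0257, and adjusted p = 0.203 with an estimated correlation). Within that list Blvrb fell from 59.4 ± 0.63 to 28.3 ± 0.36 FPKM and Hmox1 from 746 ± 9.1 to 476 ± 2.5. Further falls were those of Prdx1 from 474 ± 9.2 to 298 ± 4.4 and the ferritin gene Ftl1 from 1263 ± 20 to 735 ± 21. Pseudogenes can share reads with Prdx1 and Ftl1. Lysosome genes fell in 15 of 23 cases with 3 rises (adjusted p = 0.0156, and adjusted p = 0.199 with an estimated correlation). That call was also lost with quantile scaling (adjusted p = 0.0665). Hexa went from 106 ± 2.4 to 62.3 ± 1.3 FPKM and Ctsd from 800 ± 15 to 479 ± 13. Cell cycle genes, already low in M1, fell again in 24 of 30 cases with 3 rises (adjusted p = 0.00637, and adjusted p = 0.173 with an estimated correlation). Rrm2 went from 2.71 ± 0.22 to 0.95 ± 0.076 FPKM, Mcm2 from 2.8 ± 0.023 to 1.51 ± 0.1 and Mcm5 from 6.56 ± 0.097 to 3.94 ± 0.3.

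Thus 8 of 23 lists were called for I vs M1, and 0 held with an estimated correlation, where the lowest adjusted p was 0.0747. Among lists not called, GTPases had 4 higher and 10 lower of 18, antigen presentation 2 and 10 of 17, NF-kB 14 and 11 of 28 and inflammasome genes 4 and 6 of 13. Also not called were cholesterol synthesis at 2 and 14 of 20, liver X receptor genes at 5 and 4 of 13, ATF4 and CHOP targets at 7 and 9 of 17, chaperones at 5 and 6 of 16, heat shock at 5 and 4 of 10 and p53 targets at 3 and 11 of 17. The rest were M1 markers at 5 and 10 of 16, M2 markers at 5 and 4 of 9, cytokines, macrophage identity genes and osteoclast markers. Adjusted over the list alone, the interferon-stimulated count became 22 higher and 10 lower, the respiratory count 24 lower and the osteoclast count 4 lower, and the other lists kept their counts.

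Macrophage identity genes were lower with iodide in 8 of 12 cases and higher in 3, and the list was not called (adjusted p = 0.116), though it was with limma-voom (adjusted p = 0.029). Adgre1 fell from 103 ± 2.3 to 35.1 ± 0.75 FPKM, Cd68 from 323 ± 1.9 to 181 ± 3.1 and Lyz2 from 1138 ± 31 to 675 ± 24. Of 5 osteoclast markers 3 fell and 1 rose (adjusted p = 0.0989). Mmp9 went from 9.83 ± 0.42 to 1.73 ± 0.084 FPKM, Dcstamp from 47.7 ± 0.26 to 20 ± 0.25 and Acp5 from 2.94 ± 0.037 to 1.35 ± 0.21. Cd83, the only tested gene of the dendritic cell list, rose from 24.4 ± 0.34 to 51.8 ± 1.9 FPKM. Lck was at 3.58 ± 0.34 in M1 and 3.38 ± 0.095 in I, a difference that was not called.

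**Figure D2:**
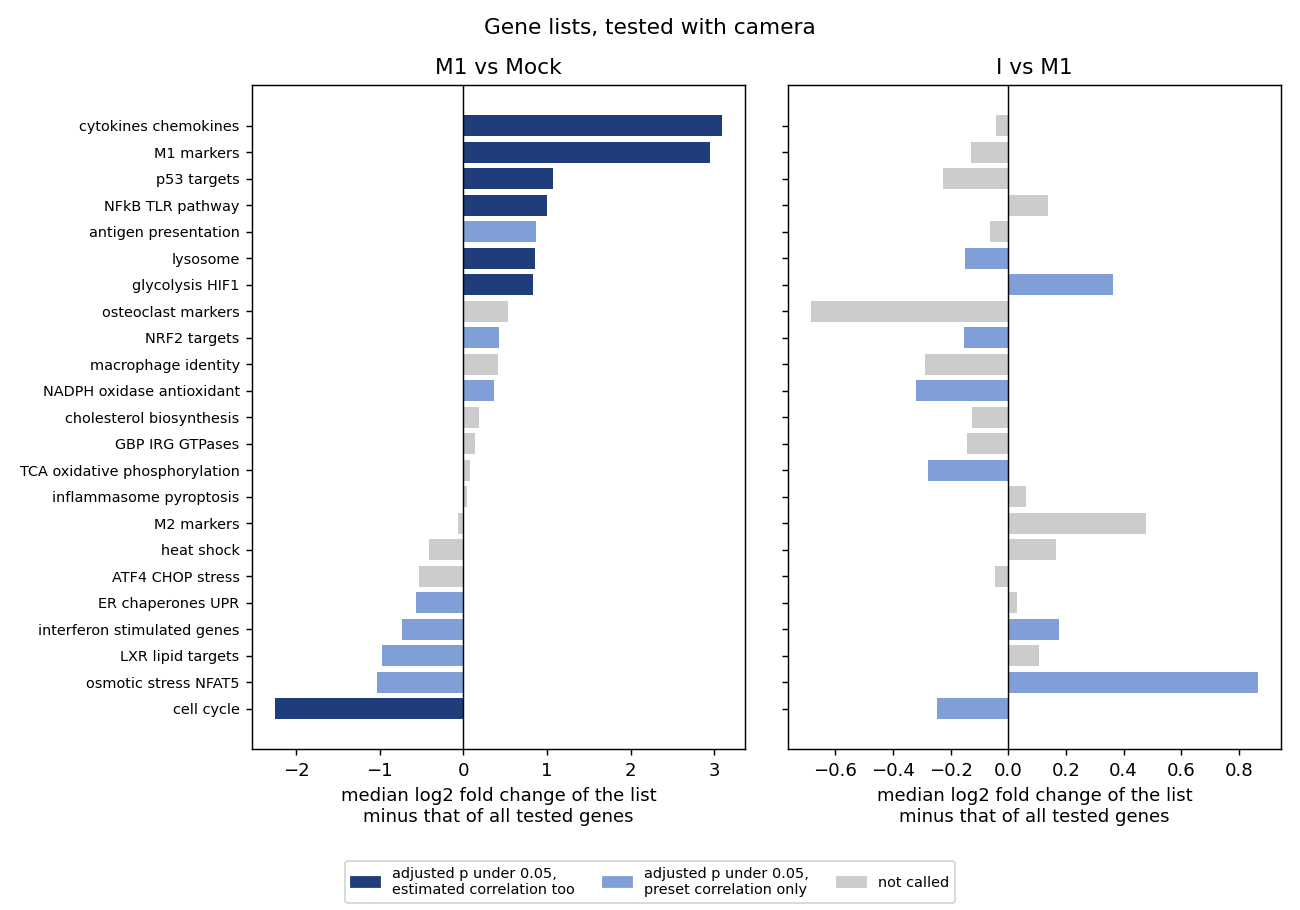
Median log2 fold change of each of 23 gene lists minus that of all tested genes (horizontal axes, log2), for M1 vs Mock and for I vs M1, with bars coloured by the camera test at a preset and at an estimated correlation. For M1 vs Mock the medians reach 3.1 for cytokines and −2.25 for cell cycle genes, and for I vs M1 the highest is 0.87 for osmotic response genes.

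Iodide moved M1-response genes both back and further. Among the 756 genes that rose at least 2-fold in M1, such as Il1b, Ccl2 and Fpr2, 358 were lower with iodide, 245 higher and 153 not called. Among the 1794 that fell, such as Akr1b3, Ranbp3l and Cxcl10, 496 were higher with iodide, 676 lower and 622 not called. In sum 854 genes moved back and 921 moved further, an order that turned with RLE scaling (826 and 810). For independent lists of these sizes the numbers back would be 297 after a rise and 446 after a fall, and the numbers further 188 and 705. Genes that fell in M1 and fell again with iodide were thus fewer than for independent lists, and the other 3 classes were larger. In 100 simulations with no iodide effect the medians were 0 and 0, which bears only on chance calls and not on the direction of real ones. The covariance of the log2 fold changes across genes was −0.0227, with a simulated median of −0.00222, so the difference was −0.0205. Part of the excess of genes moved back may come from the M1 libraries that both comparisons share. Such sharing pushes the 2 log2 fold changes in opposite directions. It therefore does not account for the excess of genes that rose in M1 and rose again with iodide (245 against 188). That excess need not be one of direction, because the independent numbers use the share of calls among all genes. Of the 756 genes 153 were not called, against 3999 of all 11156, and more calls in a class raise both of its counts. The most negative simulated covariance was −0.00368, so the shared spread between M1 libraries alone gave less than the observed −0.0227. A deviation common to all 3 M1 libraries was not simulated, so what sharing can give in that case is not known. The 3 M1 libraries do not leave 2 for each comparison, so they were not split.

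**Figure D3:**
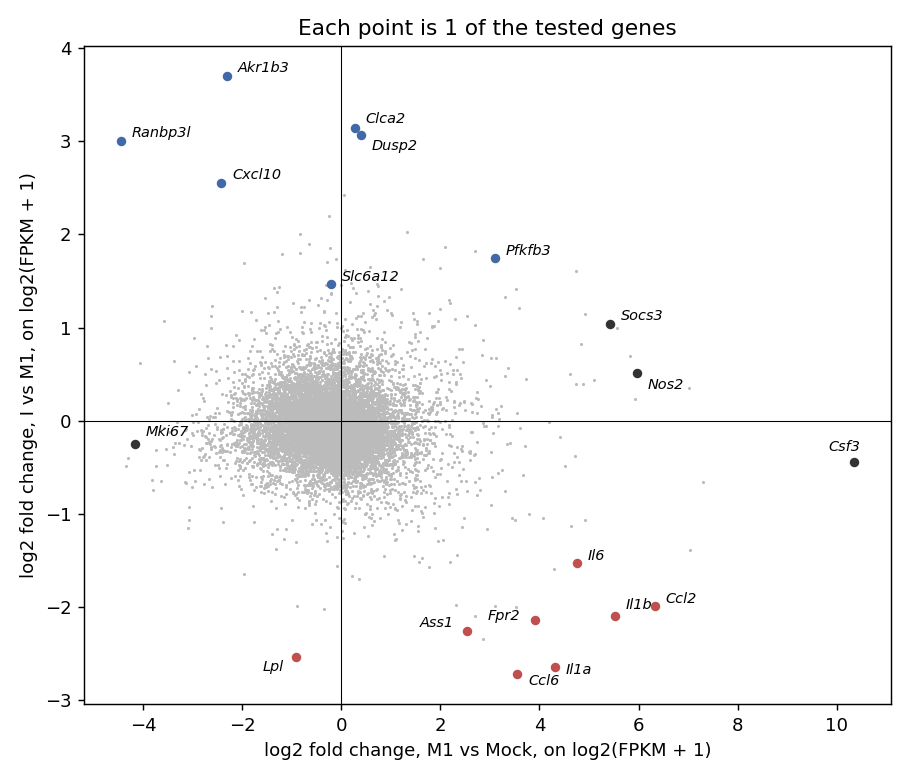
Log2 fold change of each of 11156 tested genes for M1 vs Mock (horizontal axis) and for I vs M1 (vertical axis), on log2(FPKM + 1), with named genes in colour. Akr1b3 lies at −2.31 and 3.7, Il1b at 5.51 and −2.1, and Nos2 at 5.97 and 0.52.

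Against untreated cells, iodide-treated polarized cells still had high M1 genes. Nos2 was 93.4-fold, Tnf 7.07-fold, Il1b 55.6-fold, Il6 45.7-fold, Cd86 13.2-fold and Hmox1 3.68-fold higher in I than in Mock. Csf3 reached 1465 ± 49 FPKM and Ccl2 was 25.0-fold higher. Pfkfb3 was 32.8-fold higher. Akr1b3 (2.65-fold), Slc6a12 (2.4-fold) and Hspa4l (3.42-fold) also exceeded Mock. By contrast Ranbp3l stayed at 12.9 ± 0.2 against 36.7 ± 0.2 FPKM and Mki67 at 1.79 ± 0.064 against 58.2 ± 1.1. Cxcl10 was at 88 ± 0.39 FPKM against 80.5 ± 3.1 in Mock (adjusted p = 0.00203), a call lost with quantile scaling. In total 3146 genes were higher and 6534 lower in I than in Mock, with 779 and 2008 at least 2-fold. The median gene fell by 0.3 on the log2 scale, and RLE scaling gave 4762 higher and 4785 lower, with 1299 and 1221 at least 2-fold.

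Of the 23 lists 12 were called for I vs Mock. Cytokines (20 of 23 higher and 2 lower), M1 markers (14 and 2 of 16), NF-kB (18 and 7 of 28), antigen presentation (14 and 2 of 17), glycolysis (19 and 2 of 22), p53 targets (13 and 3 of 17) and lysosome genes (15 and 5 of 23) were called higher. Cell cycle (29 of 30 lower), interferon-stimulated genes (29 of 35), liver X receptor genes (11 of 13), chaperones (15 of 16) and respiratory genes (20 of 26) were called lower. The interferon-stimulated and respiratory lists were not called with RLE scaling (adjusted p = 0.0587 and 0.367). With an estimated correlation M1 markers, glycolysis and cell cycle held (adjusted p = 0.0299 to 0.0333), and the other 9 had an adjusted p of 0.0532 to 0.252. Not called were osmotic response genes (3 higher and 6 lower of 9), NRF2 targets (11 and 7 of 19), NADPH oxidase genes (6 and 7 of 13) and M2 markers (4 and 3 of 9). The others were GTPases (7 and 10 of 18), inflammasome genes (6 and 7 of 13), cholesterol synthesis (6 and 12 of 20), ATF4 and CHOP targets (6 and 11 of 17), heat shock genes (2 and 8 of 10), macrophage identity (5 and 7 of 12) and osteoclast markers (1 and 3 of 5).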

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

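The filter of 0.5 FPKM in 3 libraries was itself chosen after seeing the data. TMM and quantile scaling and the pseudocount of 0.1 were added after seeing the data, as were upper quartile scaling, the filter of 1 FPKM, limma-voom and the fit of 6 libraries for the list tests. The other settings were chosen before. The planned DESeq2 test was not run, because the files hold FPKM and not counts.

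The number of called genes stayed within 1.5 times under each scaling, filter, pseudocount and model and at a threshold of 0.01, and requiring a log2 fold change of at least 1 left 2550 for M1 vs Mock, 204 for I vs M1 and 2787 for I vs Mock. Of the named genes, Lck in M1 vs Mock (RLE, TMM and quantile) and Cxcl10 in I vs Mock (quantile) lost their calls, and no named gene turned its direction. Higher calls for I vs Mock rose to 4762 with RLE and 4825 with TMM. The 2-fold counts depend on scaling and pseudocount. For M1 vs Mock they became 1163 higher and 1163 lower with RLE and 1174 and 1147 with TMM. For I vs Mock they became 1299 and 1221 with RLE, 1331 and 1198 with TMM, and 1202 and 1285 with quantile scaling. For I vs M1 they became 623 (294 higher, 329 lower) with limma-voom and 493 (243 and 250) at a pseudocount of 0.1. Limma-voom changes the unit, the model and the genes tested at the same time. With no minimum fold 3220 M1-response genes moved back and 3060 further. Back and further changed order with RLE (826 and 810), upper quartile (836 and 810) and TMM scaling (819 and 805). The cause was not tested for any of these changes.

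With an estimated correlation 7, 0 and 3 lists were called for M1 vs Mock, I vs M1 and I vs Mock, and with fry, which does not compare a list with other genes, 22, 20 and 22. Fry called some lists lower where an uncalled camera test pointed higher. Their median log2 fold changes, whose sign can differ from fry's direction, were −0.042 for cholesterol synthesis in M1 vs Mock. In I vs M1 they were 0.414 for M2 markers, −0.005 for inflammasome, 0.042 for liver X receptor and 0.098 for heat shock genes. In I vs Mock they were −0.215 for NADPH oxidase and −0.367 for macrophage identity genes. Calls were also gained. The heat shock list was called lower in M1 vs Mock with quantile scaling (adjusted p = 0.0105), limma-voom (0.0283) and without Mock replicate 1 (0.0491) or 2 (0.0487), and in I vs Mock with quantile scaling (0.0251). The macrophage identity list was called lower in I vs M1 with limma-voom (0.029). Medians, means and camera differed in sign for 11 uncalled lists and for 0 called ones.

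Leaving out each library in turn gave 8999 to 9565 called genes for M1 vs Mock, 6648 to 7016 for I vs M1 and 9124 to 9689 for I vs Mock, and 773 to 861 genes moved back by iodide. Same-numbered libraries did not deviate together (r of −0.115 to 0.047 across genes, 0 of 9 pairs over 0.1). With the number as a replicate block 9548, 7032 and 9663 genes were called, and 14, 8 and 12 lists. The depth of 17431070 to 25470730 fragments limits values under about 0.5 FPKM. Genes that did not reach 0.5 FPKM in at least 3 libraries were not tested. A tested gene can still lie under it in a group, as Il1b and Il6 did in Mock.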

Other observations

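All tests in this part except the splits of the libraries were chosen after the results were seen. Gene families taken by name also moved with iodide. In I vs M1, 65 of 80 cytosolic ribosomal protein genes, 66 of 77 mitochondrial ribosomal protein genes, 34 of 39 proteasome subunit genes and 29 of 36 subunit genes of respiratory complex I were lower, with medians of −0.182, −0.3, −0.18 and −0.283 relative to all genes. By contrast 8 of 11 genes of the mitochondrial genome, which encode respiratory subunits, were higher and 0 lower (median 0.438). With RLE scaling the counts were 54, 62, 30 and 28 lower for the nuclear families and 9 higher for the mitochondrial genome. Relative to genes of similar exon length the nuclear medians were −0.121, −0.248, −0.133 and −0.235. None of the 12 families was called with an estimated correlation (lowest adjusted p = 0.129), and ribosomal protein reads can be shared with pseudogenes. In M1 vs Mock 65 of 80 cytosolic ribosomal genes were higher and 5 lower, 18 and 41 of 77 mitochondrial ribosomal genes, 19 and 15 of 39 proteasome genes, 20 and 4 of 36 complex I genes, and 0 and 9 of 11 genes of the mitochondrial genome. With RLE scaling these became 77 and 1, 42 and 21, 28 and 9, 33 and 1, and 1 and 9, so the direction of the mitochondrial ribosomal family depends on the scaling. In I vs Mock 9 of the 11 genes of the mitochondrial genome were lower and 1 higher.

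Osmotic response genes rose with iodide. For 3 of the 7 that rose, Akr1b3, Slc6a12 and Hspa4l, the level in I was above Mock under each of the 5 scalings. For Akr1b3, which had fallen from 61.8 ± 0.54 to 11.7 ± 0.12 FPKM in M1, this argues against a mere return to the untreated level. Slc6a12 had fallen little in M1, from 109 ± 2.2 to 94.5 ± 2.3 FPKM. Hspa4l was already higher in M1 (12.9 ± 0.1 FPKM) than in Mock (11 ± 0.14), so these levels say little on such a return. For the other 4, Nfat5, Slc5a3, Slc38a2 and Sgk1, the level lay between M1 and Mock, so such a return cannot be told apart from a weaker response to the salt. The list stood 0.867 above all genes, yet every library with added salt received iodide, so an effect of iodide may be one of potassium or osmolarity, and the design cannot tell them apart. A culture with the same strength of another potassium salt would separate them.

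Most genes of the interferon-stimulated list were higher in Mock than in M1, though M1 cells received interferon gamma. This did not hold for interferon-inducible genes in general. Of 18 interferon-inducible GTPases 6 were higher and 8 lower in M1. Gbp2 rose from 4.63 ± 0.26 to 72.9 ± 2.9 FPKM, while Irgm2 fell from 44 ± 0.73 to 11.6 ± 0.3. At least 23 of 35 were called lower in M1 under each scaling, which argues against the library total as the whole cause, and at least 14 of 16 M1 markers were higher in M1, which argues against exchanged labels. A candidate explanation is interferon made by the Mock cells, since Ifnb1, chosen after its values were seen, was at 5.82 ± 0.65 FPKM in Mock and 0.25 ± 0.31 in M1 (log2 fold change −2.47, adjusted p = 2.95e-08). In I, Ifnb1 was at 0.3 ± 0.15 FPKM, a difference from M1 that was not called (limma adjusted p = 0.669). There 20 of the 35 genes were higher than in M1 and 9 lower, without a called change in Ifnb1. Whether interferon from the Mock cells acts on these genes was not tested, and the time of sampling is not given in the sources used here.

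Cytokine and M1 marker genes did not move evenly with iodide. Of the 31 that rose at least 2-fold in M1, at least 10 were higher and at least 16 lower in I under each scaling. This argues against an evenly weaker or evenly stronger polarization as the only change. Calls both ways were also common among all 11156 tested genes, with 2775 higher and 4382 lower, or 3478 and 3540 with RLE scaling. The counts therefore do not set these genes apart, and do not exclude such a change beside other effects. Among the higher genes of the 31, Il1rn rose from 1039 ± 30 to 1676 ± 17 FPKM, Ccl3 from 3688 ± 94 to 4925 ± 202 and Cxcl11 from 19.7 ± 0.71 to 72.4 ± 2. These 3 were chosen after their values were seen. A difference in the timing of the response stays open as a hypothesis, since the labels give no time course.

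Other splits of the 6 libraries of a comparison cannot give a share under 0.05, because 3 against 3 make 10 splits. With 6 libraries in the fit, the real split called 9517 genes for M1 vs Mock, 6805 for I vs M1 and 9638 for I vs Mock, 1 split in each case giving as many, and the highest of the others called 0.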
